A study of Mus musculus with 16 samples.

How the data were processed

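Livers of 16 male mice in 4 groups of 4 (fed WT, fed KO, fasted WT, fasted KO) were profiled with stranded poly(A) libraries made from 500 ng of RNA, per the labels' protocols. The deposited table holds counts, raw whole numbers of reads per gene made by the authors, with no normalization. Per the submitters' processing notes the tools were cutadapt 1.8, STAR 2.5.3a and HTSeq 0.9.1 on GRCm38; the strand setting and the annotation release are not given in the sources used here. Of the 53714 gene identifiers, 53619 (99.8%) were found in the mouse annotation at hand, which gave symbols and positions.

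The table also has 5 summary lines that name no gene. Of all counts per library, 32.0% to 45.8% stood in the line for reads aligned to several places. The lines for reads that met no gene and more than 1 gene held 2.98% to 4.29% and 1.05% to 1.65%. Whether the first line counts a read once or once per place is not given, so its share of reads may be smaller. Reads in these lines were left out of the gene totals, which were 19.6 to 27.4 M per library. Between libraries of a group the spread was on average 6.54 to 88.7 times the counting variance per gene (chi-square per gene after scaling by library totals, 24 pairs). This mean leaves out genes with low counts and does not show that their counting error is small. The common biological coefficient of variation was 0.138 with 12 residual degrees of freedom.

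Groups came from the sample labels, and replicate numbers were treated as names only. Genes with low counts were left out with filterByExpr of edgeR 4.0.16, which kept 13905 genes. Counts were scaled by TMM (factors 0.903 to 0.966 in WT and 1 to 1.141 in KO libraries), and all 16 libraries entered a single model with a coefficient per group. The 5 contrasts, which are fed KO minus fed WT, fasted KO minus fasted WT, fasted WT minus fed WT, fasted KO minus fed KO and the difference of the genotype effects, were tested with edgeR's quasi-likelihood F test with robust estimation. Adjusted p is by Benjamini-Hochberg over the genes tested, with a threshold of 0.05; log2 fold changes are edgeR estimates, and their standard error is the fold change divided by the square root of F. CPM and log2 CPM (prior count 2) were computed here from the deposited counts with the TMM factors. Single library measures were compared by exact two-sided permutation over all splits of 4 against 4, adjusted by Benjamini-Hochberg.

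A set of 35 gene lists of pathways, complexes, cell types, liver zones, sex bias, clock, mitochondria and genes around Slc25a47 was written from general knowledge. For each list and contrast, called members were counted with p adjusted over all genes and over the list alone. The competitive test was camera of limma 3.58.1 with the preset correlation of 0.01, adjusted over the lists of a contrast, and with a correlation estimated per list as an alternative; fry of the same package, passed at an FDR under 0.05, was run as a further test. The preset value is far below the correlations estimated for most lists (-0.051 to 0.745), so camera p with the preset value is the more lenient. Lists share members: 10 of 17 periportal genes, 7 of 31 urea cycle genes and 5 of 21 pericentral genes also stand in another list.

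Genes named in the text were chosen by rule. In each contrast the rule takes the 8 largest rises and falls (5 for the interaction) among called genes with average log2 CPM of at least 1 and, outside the interaction, no overlap between the groups, leaving out predicted genes and pseudogenes. It adds Slc25a47, the genes around it, and up to 4 called members of each list with the smallest p. Exceptions are Fgf21, Gdf15 and the other tRNA synthetases, chosen after their values were seen, and Igf1, Igfals, Socs2 and Cish, picked for a test before theirs were seen. The pancreatic, Y-linked and single-copy gene sets were also put together after results were seen.

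The test, contrasts, lists, naming rule and most alternatives were fixed before the data were examined. Those alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, no robust estimation, the replicate number as a block, each library left out in turn, only the 8 libraries compared, adjusted p under 0.01, DESeq2 size factors and estimated correlation for the lists, and a higher level filter for the agreement of genotype effects. Scaling by library totals alone and leaving out the fasted WT libraries with pancreatic transcripts were added after seeing the data. The libraries left out were fasted WT replicates 2 and 4, which had the most of these transcripts. Other splits of the libraries were refitted to see how many genes chance groupings of mice call.

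The procedure was tested on simulated data with 13508 genes tested and 200 changed. It recovered 32 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 60 of 66 changed 4-fold, and called 5 unchanged genes, with 0 genes called in a contrast without change. A list raised 1.5-fold had a camera p of 1.92e-51 (8.77e-10 with an estimated correlation), and an unchanged list 0.963. Genes were simulated independently, so these values do not test camera on lists whose members are correlated. With 200 genes changed, up and down, the simulation also does not test the scaling where many genes change. Computations used R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9.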

Results

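Polyadenylated RNA was sequenced from the livers of 16 male C57BL/6 mice aged 9 weeks, in a design that crossed 2 genotypes with 2 feeding states. Knockout (KO) mice lacked Slc25a47, a liver-enriched member of the mitochondrial carrier family, in hepatocytes, and the other mice served as controls (WT). Each genotype was sampled after free access to chow (fed) or after an overnight fast (fasted), which gave 4 groups of 4 libraries: fed WT, fed KO, fasted WT and fasted KO. Between 19.6 and 27.4 M reads per library were assigned to genes, and the group means were 23.0 ± 3.02 M (SD, n = 4) in fed WT, 22.01 ± 1.91 M in fed KO, 21.6 ± 2.20 M in fasted WT and 23.5 ± 0.704 M in fasted KO. Of the 53714 genes counted, 13905 had enough reads to be tested.

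The targeted gene, Slc25a47 (ENSMUSG00000048856), lies on chromosome 12 of GRCm38 from 108836046 to 108856815 on the forward strand, and its protein-coding transcripts start at 108851129 or 108851139. Its level was 636.5 ± 154 CPM (counts per M gene reads after TMM scaling; SD, n = 4) in fed WT and 126 ± 32.3 CPM in fed KO livers. After the fast it was 949.5 ± 129 CPM in WT and 261.4 ± 77.2 CPM in KO livers. The KO level was thus lower by a log2 fold change of -2.34 ± 0.25 (SE; edgeR adjusted p = 1.32e-05) in the fed and -1.86 ± 0.25 (adjusted p = 8.06e-05) in the fasted state, and no KO library reached the lowest WT library. Gene-level counts do not separate exons. Any reads from a shortened transcript or from cells outside the knockout would be part of the remaining level, and neither was measured. The fasting rise of Slc25a47 was 1.05 ± 0.24 in KO livers (adjusted p = 0.00319), while its value of 0.58 ± 0.24 in WT livers did not pass the test (adjusted p = 0.078). The WT value did pass when only the 8 libraries compared were fitted. The difference between the KO and WT values was 0.48 ± 0.34 (adjusted p = 0.529).

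Of the 9 tested genes around Slc25a47, Wars (ENSMUSG00000021266), the cytosolic tryptophanyl-tRNA synthetase gene whose end lies 3214 bp beyond that of Slc25a47 on the opposite strand, fell by 0.82 ± 0.11 in fed and by 1.0 ± 0.11 in fasted KO livers on the log2 scale. It was also lower after the fast, by a log2 fold change of -0.70 ± 0.11 in WT and -0.88 ± 0.11 in KO livers. Of 19 other cytosolic tRNA synthetase genes, a set picked after the Wars values were seen, 6 were higher and 3 lower in fed and 11 higher and 0 lower in fasted KO livers. In the locus list, 2 genes were higher and 2 lower in the fed genotype comparison, over all genes and adjusted over the list alone. The fasted comparison had the same counts, but 0 higher and 2 lower without the fasted WT libraries with pancreatic transcripts. With library totals the counts were 5 and 2 fed and 4 and 2 fasted. The list was not called by camera in either (adjusted p = 0.662 and 0.763), and its other called members in the fed state were Yy1 at 0.39 ± 0.10, Rian at 1.12 ± 0.32 and Cyp46a1 at -1.24 ± 0.39. The Cyp46a1 call was lost without fed KO replicate 3 (adjusted p = 0.0771) or fed WT replicate 3 (adjusted p = 0.0972).

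The first principal component held 35.3% of the variance of log2 CPM and separated fasted from fed libraries, and the second held 30.9% and separated KO from WT libraries.

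**Figure D1:**
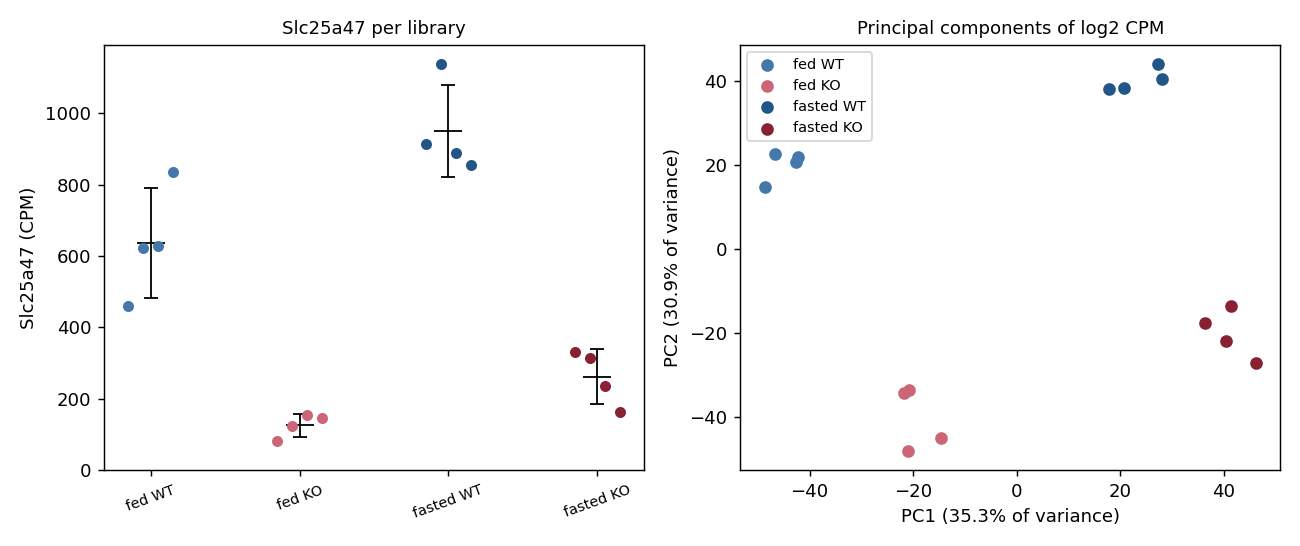
Left, Slc25a47 in CPM for each library, with the mean and SD of the 4 libraries per group; the KO groups average 126 and 261.4 CPM and the WT groups 636.5 and 949.5 CPM. Right, scores of the 16 libraries on the first and second principal components of log2 CPM (35.3% and 30.9% of the variance), where the 4 groups do not overlap.

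The comparison of fed KO with fed WT livers asked what loss of hepatic Slc25a47 does to liver transcripts under chow feeding. Psat1 (ENSMUSG00000024640), which encodes an enzyme of serine synthesis, rose from 0.647 ± 0.304 to 15.8 ± 1.37 CPM (SD, n = 4), a log2 fold change of 4.61 ± 0.25 (SE). Elovl3 (ENSMUSG00000038754), a fatty acid elongase gene with higher levels in male than in female mouse liver, fell from 853 ± 84.2 to 129 ± 29.6 CPM, by 2.73 ± 0.20 on the log2 scale. Cyp2b9 (ENSMUSG00000040660), a cytochrome P450 gene with higher levels in female liver, rose from 0.162 ± 0.080 to 82.8 ± 25.5 CPM, by 8.95 ± 0.64. The basement membrane collagen IV genes Col4a1 and Col4a2 were higher, at 1.25 ± 0.11 and 1.14 ± 0.13, and Apoa1, which encodes the main protein of high-density lipoprotein, fell by 1.07 ± 0.10.

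With edgeR, 4299 of 13905 genes were called in the fed genotype comparison, 1948 higher and 2351 lower in KO, and 482 and 392 of them differed at least 2-fold. The balance of directions rested on the scaling. With library totals alone, a setting chosen after seeing the data, the median of all genes moved from -0.008 to 0.215 and the split became 4886 higher and 915 lower, so that small changes are relative to the TMM scaling (trimmed mean of M values). Genes with large changes included the fetal mRNA-binding protein gene Igf2bp3 at 5.30 ± 0.38, the synaptic adhesion gene Tenm4 at 8.24 ± 0.61, the adipokine gene Serpina12 at -4.16 ± 0.29 and Moxd1, with wide spread between libraries, at -4.46 ± 1.15. The vomeronasal receptor gene Vmn2r3 (ENSMUSG00000091572) had 2 counts over the 4 fed WT libraries and 15153 over the 4 fed KO libraries, a ratio of 6750 with a 95% counting interval from 1870 to 55800, which covers counting error only.

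Genes of the integrated stress response, targets of ATF4, rose as a group: of 27 tested, 21 were higher and 2 lower, and 21 and 2 when adjusted over the list alone (camera adjusted p = 6.79e-12; adjusted p = 0.0308 with an estimated correlation). Besides Psat1, the transcription factor gene Atf5 rose by 2.05 ± 0.12, the amino acid transporter subunit gene Slc3a2 by 1.62 ± 0.11 and the lipoprotein receptor gene Vldlr by 4.63 ± 0.29. The hepatokine genes Fgf21 and Gdf15, picked after their values were seen, rose by 3.62 ± 0.42 and 1.34 ± 0.35. Mitochondrial chaperones and proteases had 5 higher and 1 lower of 16, with the same counts adjusted over the list alone (adjusted p = 0.0166; adjusted p = 0.325 with an estimated correlation), and 11 and 0 with library totals. The matrix protease gene Lonp1 rose by 1.65 ± 0.11 and the chaperone gene Hspa9 by 1.17 ± 0.09.

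Extracellular matrix genes had 25 higher and 1 lower of 34, and 30 and 1 when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 4.63e-11; adjusted p = 0.158 with an estimated correlation). Among markers of hepatic stellate cells, 10 of 14 were higher and 0 lower, or 11 and 0 adjusted over the list alone (adjusted p = 2.47e-05; adjusted p = 0.0308 with an estimated correlation). Pdgfrb, a stellate cell growth factor receptor gene, rose by 0.59 ± 0.09 and the pericyte marker gene Rgs5 by 0.59 ± 0.08. Endothelial markers had 2 higher and 0 lower of 14 with a median of 0.06 (adjusted p = 0.272), and 8 and 0 with library totals. Macrophage markers had 4 higher and 1 lower of 19, or 3 and 0 adjusted over the list alone (adjusted p = 0.0166; adjusted p = 0.615 with an estimated correlation). Cd9 stood at 0.90 ± 0.11. The macrophage call was lost with library totals (11 higher and 0 lower, adjusted p = 0.127), without fed KO replicate 1 (0.0556) and without fed WT replicate 4 (0.073).

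Hepatocyte marker genes had 1 higher and 9 lower of 22, or 1 and 12 adjusted over the list alone (camera adjusted p = 9.67e-05; adjusted p = 0.293 with an estimated correlation), and with library totals the median was -0.03 with 1 higher and 6 lower. Ahsg, which encodes the plasma protein fetuin-A, went the other way at 0.81 ± 0.08. Enzymes of the urea cycle and amino acid breakdown had 1 higher and 16 lower of 31, or 1 and 17 adjusted over the list alone (adjusted p = 0.00104; adjusted p = 0.509 with an estimated correlation), but 9 higher and 8 lower with library totals. Tdo2 and Haao, enzyme genes of tryptophan breakdown, had log2 fold changes of -0.79 ± 0.11 and -0.78 ± 0.08. Nuclear genes of the respiratory complexes had 1 higher and 23 lower of 75, with the same counts adjusted over the list alone (adjusted p = 0.000623; adjusted p = 0.615 with an estimated correlation), but 19 higher and 3 lower with library totals, where the median moved from -0.11 to 0.11 and the call was lost (adjusted p = 0.687). Of the mitochondrial genome's own protein genes 13 were listed and only 7 tested. They had 0 higher and 6 lower of 7, or 0 and 7 adjusted over the list alone (adjusted p = 0.000736; adjusted p = 0.305 with an estimated correlation), and 0 and 3 with library totals. mt-Nd4 stood at -0.52 ± 0.08. Genes of hepatocytes around the portal vein had 1 higher and 10 lower of 17, or 2 and 10 adjusted over the list alone (adjusted p = 0.000653; adjusted p = 0.305 with an estimated correlation), and 3 and 9 with library totals. Cyp2f2 stood at -1.03 ± 0.14 and Pigr at -1.36 ± 0.14.

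Genes with higher levels in male liver were all lower in fed KO livers: 20 of 20 over all genes and 20 adjusted over the list alone, with a median of -2.43 (camera adjusted p = 2.93e-16; adjusted p = 0.0868 with an estimated correlation). Besides Elovl3, the complement gene C6 fell by 2.54 ± 0.23, the major urinary protein gene Mup21 by 3.35 ± 0.26 and Cyp7b1, an oxysterol hydroxylase gene, by 3.07 ± 0.36. Major urinary protein genes together took 2.93% ± 0.215 of gene reads in fed WT and 0.742% ± 0.306 in fed KO livers (SD, n = 4 each). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 allows (adjusted p = 0.0616 over 28 tests of library measures). Reads that aligned to several places are not in this share. Genes with higher levels in female liver had 13 higher and 0 lower of 17, or 14 and 0 adjusted over the list alone, with a median of 2.16, also with 3 members near 0 counts set at their bound (adjusted p = 2.70e-11; adjusted p = 0.0232 with an estimated correlation). Cyp17a1, a steroid hydroxylase gene of that list, rose by 2.04 ± 0.24.

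Proliferation genes had 15 higher and 0 lower of 23, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.95e-07; adjusted p = 0.305 with an estimated correlation). Cdc20 stood at 2.87 ± 0.50 and Ccnb1 at 2.67 ± 0.54. Fetal liver and tumour genes had 8 higher and 0 lower of 14, or 10 and 0 adjusted over the list alone (adjusted p = 1.24e-06; adjusted p = 0.0868 with an estimated correlation). The imprinted gene H19 stood at 4.89 ± 0.66. Targets of p53 had 9 higher and 0 lower of 15, or 9 and 1 adjusted over the list alone (adjusted p = 0.0166; adjusted p = 0.305 with an estimated correlation, and 0.134 with library totals). The apoptosis gene Bax stood at 0.52 ± 0.12. Drug-metabolising enzymes had 6 higher and 0 lower of 16, with the same counts adjusted over the list alone (adjusted p = 0.0111; adjusted p = 0.325 with an estimated correlation), and 10 and 0 with library totals. Cyp2b10 stood at 4.05 ± 0.61 and Cyp3a11 at 1.91 ± 0.20. Interferon-stimulated genes had 1 higher and 11 lower of 22, or 1 and 12 adjusted over the list alone (adjusted p = 0.00434; adjusted p = 0.615 with an estimated correlation), and 1 and 7 with library totals. Ifit1 stood at -1.31 ± 0.24 and Mx2 at -1.07 ± 0.20.

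Fatty acid oxidation genes, with 12 higher and 5 lower of 33 or 14 and 6 adjusted over the list alone, lay at the threshold (camera adjusted p = 0.049; adjusted p = 0.687 with an estimated correlation). That call was lost with library totals (20 higher and 3 lower, adjusted p = 0.0546) and without fed KO replicate 3 (0.0588), fed KO replicate 4 (0.176), fed WT replicate 1 (0.163) or fed WT replicate 2 (0.0553), and its members included the microsomal hydroxylase gene Cyp4a14 at 5.02 ± 0.61. Bile acid genes had 1 higher and 9 lower of 20, or 2 and 9 adjusted over the list alone (adjusted p = 0.049; adjusted p = 0.509 with an estimated correlation), but 4 higher and 6 lower with library totals, where the median moved from -0.19 to 0.03. Cyp27a1 stood at -0.81 ± 0.09. The bile acid call was lost without fed KO replicate 1 (0.0752), fed KO replicate 2 (0.0573), fed WT replicate 3 (0.0752) or fed WT replicate 4 (0.073), and with the replicate number as a block (0.0524).

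Other lists were not called in the fed genotype comparison, but with library totals 3 of them were: mitochondrial ribosome (adjusted p = 0.000742), acute phase (0.00291) and clock genes (0.019). By adjusted p over camera's lists, the closest were NRF2 and glutathione genes at 0.0523 with 9 higher and 3 lower of 20, bile duct markers at 0.066 with 0 of 10 called, mitochondrial ribosome genes at 0.167 with 9 higher and 4 lower of 77, and acute phase genes at 0.196 with 2 higher and 9 lower of 23. Gluconeogenic genes (adjusted p = 0.207), clock genes (0.213) and endoplasmic reticulum chaperones (0.232) had 2, 0 and 0 members higher and 6, 4 and 2 lower. Lipogenic genes (0.311), red blood cell transcripts (0.366), glycolytic enzymes (0.527) and pericentral genes (0.531) had 3, 0, 4 and 5 higher and 7, 1, 2 and 2 lower. Cholesterol synthesis genes (0.683), lymphocyte and neutrophil markers (0.854) and other mitochondrial carriers (0.923) had 1, 0 and 5 higher and 2, 1 and 7 lower. With library totals these splits moved for the mitochondrial carriers to 17 higher and 0 lower, for the mitochondrial ribosome to 44 and 0, for pericentral genes to 11 and 1, for glycolytic enzymes to 9 and 2, for bile duct markers to 7 and 0 and for cholesterol synthesis to 3 and 0. They moved to 12 and 2 for NRF2 and glutathione genes, 6 and 5 for lipogenic, 4 and 4 for gluconeogenic, 3 and 6 for acute phase and 3 and 2 for clock genes, and 2 and 1 for endoplasmic reticulum chaperones. The median and mean of the lymphocyte and neutrophil list differed in sign at 0.21 and -0.10.

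The same question was asked after an overnight fast by comparing fasted KO with fasted WT livers. Psat1 was again higher in KO livers, at 22.6 ± 5.38 against 0.834 ± 0.280 CPM (SD, n = 4), a log2 fold change of 4.75 ± 0.24 (SE). Nupr1, a stress-response gene, rose by 5.69 ± 0.50 and Serpina7, which encodes thyroxine-binding globulin, by 6.18 ± 0.31. The endoplasmic reticulum chaperone genes Calr and Pdia3 were lower, at -0.84 ± 0.11 and -0.78 ± 0.09 with all libraries. The median of the chaperone list moved from -0.59 to -0.36 without fasted WT replicates 2 and 4, which carried pancreatic transcripts as described below.

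With edgeR, 3929 genes were called in the fasted genotype comparison, 1918 higher and 2011 lower, with 441 and 268 of them at least 2-fold. With library totals the split became 4301 higher and 902 lower, and the median of all genes moved from 0.011 to 0.198. A pair of libraries of the fasted WT group carried the most transcripts of pancreatic digestive enzymes: 15 such genes summed to 1730 CPM in fasted WT replicate 2 and 471 CPM in fasted WT replicate 4. Lower sums stood in fasted KO replicate 1 (72.8 CPM), fasted WT replicate 3 (35.3 CPM) and fed KO replicate 3 (16.9 CPM), which were kept in all such refits. Without fasted WT replicates 2 and 4, called the pancreas-transcript libraries here, 3197 genes were called, 1558 higher and 1639 lower.

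Integrated stress response genes had 22 higher and 1 lower of 27, with the same counts adjusted over the list alone (camera adjusted p = 2.24e-16; adjusted p = 0.0197 with an estimated correlation). Slc3a2 stood at 2.15 ± 0.11, Atf5 at 1.68 ± 0.12 and Vldlr at 3.74 ± 0.25. Mitochondrial chaperones and proteases had 5 higher and 0 lower of 16, with the same counts adjusted over the list alone (adjusted p = 0.0113; adjusted p = 0.294 with an estimated correlation), and 10 and 0 with library totals. Lonp1 stood at 1.36 ± 0.11. Endoplasmic reticulum chaperones had 0 higher and 12 lower of 18, or 0 and 14 adjusted over the list alone (adjusted p = 2.63e-06; adjusted p = 0.309 with an estimated correlation). Without the pancreas-transcript libraries they had 1 higher and 7 lower, and the median moved from -0.59 to -0.36 (adjusted p = 0.00201). Male-biased genes had 0 higher and 19 lower of 20, also adjusted over the list alone, with a median of -1.83 (adjusted p = 2.85e-15; adjusted p = 0.271 with an estimated correlation). Elovl3 stood at -1.93 ± 0.20, Cyp7b1 at -2.96 ± 0.36 and Mup21 at -2.67 ± 0.25. The major urinary protein share was 2.39% ± 0.331 in fasted WT and 0.594% ± 0.161 in fasted KO livers (SD, n = 4 each; exact two-sided permutation p = 0.0286, adjusted p = 0.0616). Female-biased genes had 8 higher and 2 lower of 17, or 9 and 2 adjusted over the list alone, with a median of 1.0 (adjusted p = 0.00182; adjusted p = 0.275 with an estimated correlation). Cyp2b9 stood at 8.48 ± 0.65 and Fmo2, one of the lower members, at -0.70 ± 0.19.

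Matrix genes had 14 higher and 1 lower of 34, or 17 and 1 adjusted over the list alone (camera adjusted p = 2.63e-06; adjusted p = 0.275 with an estimated correlation), and 26 and 0 with library totals. Col4a1 stood at 1.06 ± 0.12 and the collagen VI gene Col6a3 at 0.63 ± 0.11. Stellate cell markers had 7 higher and 0 lower of 14, or 10 and 1 adjusted over the list alone (adjusted p = 0.00415; adjusted p = 0.275 with an estimated correlation). Angptl6 stood at 0.75 ± 0.17. Proliferation genes had 9 higher and 0 lower of 23, also adjusted over the list alone (adjusted p = 0.000307; adjusted p = 0.392 with an estimated correlation), 15 and 0 with library totals and 4 and 0 without the pancreas-transcript libraries. The cyclin gene Ccnd1 stood at 1.76 ± 0.24. Targets of p53 had 8 higher and 0 lower of 15, also adjusted over the list alone (adjusted p = 0.00756; adjusted p = 0.275 with an estimated correlation, and 0.0582 with library totals), with Aen, a nuclease gene, at 1.27 ± 0.17. Fetal liver genes had 6 higher and 1 lower of 14, also adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.275 with an estimated correlation). Igf2bp3 stood at 5.50 ± 0.37. Lipogenic genes had 9 higher and 0 lower of 20, or 10 and 2 adjusted over the list alone (adjusted p = 0.0339; adjusted p = 0.473 with an estimated correlation). The glycolytic gene Pklr stood at 0.67 ± 0.14. The lipogenic call was lost with library totals (adjusted p = 0.14) and without fasted WT replicate 3 (0.0529).

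Lower in fasted KO livers were nuclear genes of the respiratory complexes, with 0 higher and 34 lower of 75 or 0 and 43 adjusted over the list alone (camera adjusted p = 3.12e-13; adjusted p = 0.275 with an estimated correlation), and 1 and 15 with library totals. Sdhd, a succinate dehydrogenase subunit gene, fell by 0.59 ± 0.07 and Cox6b1, a cytochrome c oxidase subunit gene, by 0.60 ± 0.08. Mitochondrial genome protein genes had 0 higher and 5 lower of 7, also adjusted over the list alone (adjusted p = 0.00182; adjusted p = 0.294 with an estimated correlation), and 0 and 3 with library totals. Urea cycle and amino acid breakdown genes had 0 higher and 20 lower of 31, or 1 and 20 adjusted over the list alone (adjusted p = 1.40e-07; adjusted p = 0.275 with an estimated correlation), and 4 and 15 with library totals. The tyrosine breakdown gene Hgd stood at -0.94 ± 0.12. Hepatocyte markers had 1 higher and 12 lower of 22, or 1 and 15 adjusted over the list alone, and 3 and 6 with library totals (adjusted p = 0.000879; adjusted p = 0.275 with an estimated correlation). Apoa1 stood at -0.77 ± 0.10. Periportal genes had 1 higher and 11 lower of 17, or 1 and 13 adjusted over the list alone (adjusted p = 1.00e-05; adjusted p = 0.275 with an estimated correlation). Pigr stood at -1.15 ± 0.14. Pericentral genes had 3 higher and 10 lower of 21, or 4 and 11 adjusted over the list alone, and 4 and 6 with library totals (adjusted p = 0.0219; adjusted p = 0.435 with an estimated correlation). The ornithine aminotransferase gene Oat stood at -0.64 ± 0.10.

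Bile acid genes had 2 higher and 10 lower of 20, or 2 and 11 adjusted over the list alone (camera adjusted p = 0.00182; adjusted p = 0.275 with an estimated correlation), and 3 and 6 with library totals. Cyp27a1 stood at -0.63 ± 0.09. Interferon-stimulated genes had 0 higher and 9 lower of 22, also adjusted over the list alone (adjusted p = 0.0037; adjusted p = 0.573 with an estimated correlation), and 2 and 6 with library totals. Ifit1 stood at -1.53 ± 0.25. Gluconeogenic genes had 1 higher and 7 lower of 15, also adjusted over the list alone (adjusted p = 0.00667; adjusted p = 0.327 with an estimated correlation), and 2 and 4 with library totals, with Pck1, the cytosolic enzyme gene of the pathway, at -0.62 ± 0.13. The gluconeogenic call was lost without the pancreas-transcript libraries (adjusted p = 0.0511). The remaining 15 lists were not called in this comparison. Among them, macrophage markers came closest (adjusted p = 0.0608) with 3 higher and 0 lower of 19, fatty acid oxidation genes had 3 higher and 4 lower of 33 (0.582), endothelial markers 1 and 0 of 14 (0.788) and the mitochondrial ribosome 13 and 7 of 77 (0.763). With library totals these became 7 and 0, 9 and 0, 7 and 0, and 35 and 1 in that order, and the mitochondrial ribosome was called (adjusted p = 0.0322). For the fatty acid oxidation, NRF2, drug-metabolising, red blood cell and leukocyte lists the median, mean and camera direction differed in sign.

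**Figure D2:**
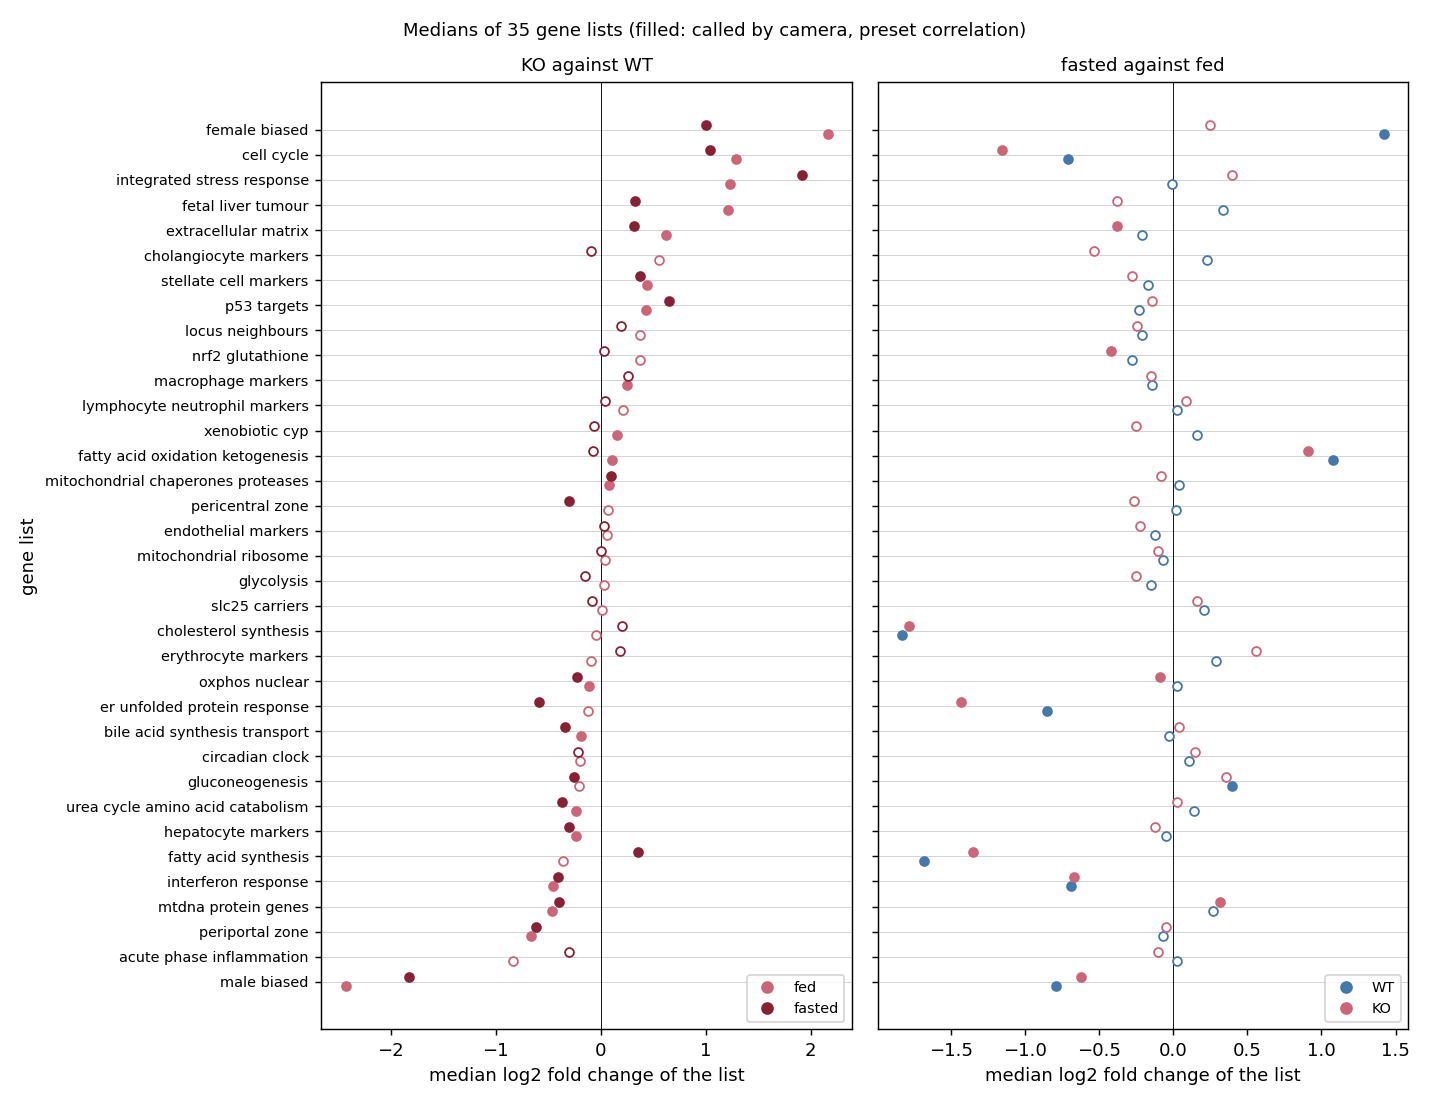
Median log2 fold change (horizontal axis) of each of 35 gene lists (vertical axis), left for KO against WT in fed and fasted livers and right for fasted against fed in WT and KO livers; filled points were called by camera with the preset correlation of 0.01. In fed livers the medians of the male-biased and female-biased lists were -2.43 and 2.16; with library totals the medians of all genes in the left panel move up by about 0.2, and some just below 0, such as that of the respiratory complexes in the fed state (-0.11 to 0.11), change sign.

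Across 13905 genes the genotype effects in fed and fasted livers, which share no library, correlated with Pearson r = 0.614 and Spearman rho = 0.601, where genes are not independent replicates. Genes called in both states in the same direction were 1020 higher and 1217 lower, against 268.7 and 340 for independent lists. In opposite directions 35 were called. Both contrasts share each gene's estimated spread in a single fit, which can raise the overlap, so the counts for independent lists are a reference only. The genotype calls shared by both states included Vmn2r3, with 5 counts over the fasted WT and 15611 over the fasted KO libraries, and Mup12 at -3.89 ± 0.38 fed and -3.88 ± 0.38 fasted. Without the filter on low counts the correlation was 0.206.

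**Figure D3:**
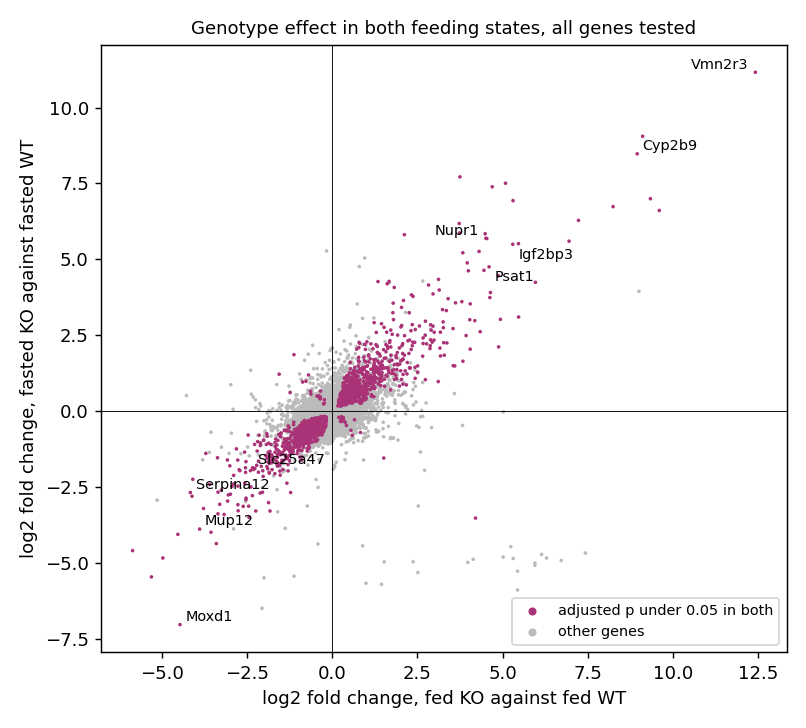
Log2 fold change of KO against WT in fed (horizontal) and fasted (vertical) livers for 13905 genes; coloured points were called in both states. Genes lie along the diagonal (Pearson r = 0.614), and the value of Vmn2r3, which had 2 counts in fed WT livers, is a model estimate near the detection limit.

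The fasting response of control livers was read from fasted WT against fed WT. Cidec, a lipid droplet protein gene, rose from 0.863 ± 0.265 to 55.4 ± 14.3 CPM (SD, n = 4), a log2 fold change of 5.98 ± 0.27 (SE). Ehhadh, a peroxisomal fatty acid oxidation enzyme gene, rose by 4.47 ± 0.23, Cyp4a14 by 8.05 ± 0.70 and Cpt1a, which encodes the entry step of mitochondrial fatty acid oxidation, by 1.28 ± 0.08. Fdps, of cholesterol synthesis, fell from 17.0 ± 2.13 to 1.10 ± 0.577 CPM, by 3.93 ± 0.23 on the log2 scale, and the lipogenic genes Thrsp and Fasn had log2 fold changes of -4.25 ± 0.31 and -3.36 ± 0.21.

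With edgeR, 4799 genes were called in the WT fasting comparison, 2252 higher and 2547 lower, with 539 and 511 at least 2-fold, and 1861 and 2891 with library totals. Fatty acid oxidation genes had 29 higher and 0 lower of 33, or 30 and 1 adjusted over the list alone (camera adjusted p = 8.73e-24; adjusted p = 0.138 with an estimated correlation). The carnitine carrier gene Slc25a20 stood at 1.27 ± 0.10. Cholesterol synthesis genes had 0 higher and 22 lower of 24, or 1 and 23 adjusted over the list alone (adjusted p = 1.99e-18; adjusted p = 0.138 with an estimated correlation). Dhcr7 stood at -1.79 ± 0.13. Lipogenic genes had 1 higher and 17 lower of 20, also adjusted over the list alone (adjusted p = 7.53e-12; adjusted p = 0.113 with an estimated correlation). Pklr stood at -2.66 ± 0.14. Endoplasmic reticulum chaperones had 0 higher and 17 lower of 18, or 0 and 18 adjusted over the list alone (adjusted p = 2.61e-10; adjusted p = 0.384 with an estimated correlation). Pdia6 stood at -1.44 ± 0.12. Interferon-stimulated genes had 0 higher and 15 lower of 22, or 0 and 17 adjusted over the list alone (adjusted p = 4.65e-05; adjusted p = 0.735 with an estimated correlation). Bst2 stood at -1.05 ± 0.14 and Oas2 at -1.37 ± 0.21. Gluconeogenic genes had 8 higher and 0 lower of 15, or 10 and 0 adjusted over the list alone (adjusted p = 0.010; adjusted p = 0.735 with an estimated correlation, and 0.0608 without the pancreas-transcript libraries). The pyruvate carboxylase gene Pcx stood at 0.87 ± 0.08.

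Male-biased genes had 1 higher and 12 lower of 20 after the fast in WT livers, also adjusted over the list alone (camera adjusted p = 0.000303; adjusted p = 0.735 with an estimated correlation), with Hsd3b5, a steroid enzyme gene, at -4.46 ± 0.54. Female-biased genes had 9 higher and 0 lower of 17, also adjusted over the list alone, with a median of 1.42, or 1.39 with 3 members near 0 counts set at their bound (adjusted p = 6.12e-05; adjusted p = 0.138 with an estimated correlation). Cyp17a1 stood at 3.09 ± 0.24. Proliferation genes had 1 higher and 7 lower of 23, or 1 and 8 adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.934 with an estimated correlation), and 0 and 2 without the pancreas-transcript libraries. Rrm2 stood at -1.15 ± 0.22. The proliferation call was lost without fasted WT replicate 3 (adjusted p = 0.0555) or fed WT replicate 1 (0.0636). The other 26 lists were not called, with matrix genes closest (adjusted p = 0.0506) at 1 higher and 12 lower of 34. Without the pancreas-transcript libraries, camera also called mitochondrial genome protein genes (adjusted p = 0.0173, against 0.0847 with all libraries). Pancreatic enzyme genes also rose in this contrast: 14 of 14 tested were called higher, with Ctrb1 and Cela3b at 0 counts over the 4 fed WT libraries. Against a floor of 3 counts over the group, their pooled counts were at least 2350-fold and 847-fold higher, which leaves out the spread between libraries. The levels of the pancreatic enzyme genes came mainly from fasted WT replicates 2 and 4, and the calls of Ctrb1 and Cela3b were lost without replicate 2 (adjusted p = 0.0611 and 0.0639) and with the replicate number as a block (0.0833 and 0.0807). Their log2 fold changes, at 13.92 ± 4.06 and 12.44 ± 3.64 with all libraries, were 12.14 ± 4.19 and 10.71 ± 3.75 without replicate 2 and 13.64 ± 4.99 and 12.13 ± 4.39 with the block (SE). Without fasted WT replicates 2 and 4 they were 8.95 ± 5.04 (adjusted p = 0.242) and 7.57 ± 4.57 (0.273). Fasted WT replicate 3, with Ctrb1 at 5.13 and Cela3b at 1.92 CPM, stayed in that fit.

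The fasting response of knockout livers was read from fasted KO against fed KO. Cidec rose from 0.901 ± 0.157 to 76.9 ± 16.2 CPM (SD, n = 4), a log2 fold change of 6.40 ± 0.26 (SE), and Cpt1a rose by 1.54 ± 0.08. Ehhadh was higher by 3.15 ± 0.22 and Inhbe, which encodes a hepatic activin subunit, by 3.23 ± 0.25. Fdps and Fasn were lower at -3.09 ± 0.20 and -2.87 ± 0.20, and Calr at -1.70 ± 0.11.

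With edgeR, 5754 genes were called in the KO fasting comparison, 2935 higher and 2819 lower, and 2216 and 3601 with library totals. Fatty acid oxidation genes had 30 higher and 0 lower of 33, also adjusted over the list alone (camera adjusted p = 6.06e-18; adjusted p = 0.261 with an estimated correlation). Cholesterol synthesis genes had 0 higher and 23 lower of 24, or 1 and 23 adjusted over the list alone (adjusted p = 4.41e-16; adjusted p = 0.261 with an estimated correlation), and lipogenic genes 3 and 15 of 20, also adjusted over the list alone (adjusted p = 5.33e-07; adjusted p = 0.261 with an estimated correlation). Endoplasmic reticulum chaperones had 0 higher and 17 lower of 18, also adjusted over the list alone (adjusted p = 2.06e-13; adjusted p = 0.266 with an estimated correlation). Hsp90b1 stood at -1.01 ± 0.10. Matrix genes had 0 higher and 17 lower of 34, or 0 and 18 adjusted over the list alone (adjusted p = 0.000117; adjusted p = 0.583 with an estimated correlation). Col4a1 stood at -0.72 ± 0.11 and Col6a3 at -0.85 ± 0.10. Proliferation genes had 1 higher and 18 lower of 23, or 1 and 19 adjusted over the list alone (adjusted p = 0.000436; adjusted p = 0.583 with an estimated correlation). Rrm2 stood at -1.84 ± 0.22. Interferon-stimulated genes had 0 higher and 15 lower of 22, or 0 and 19 adjusted over the list alone (adjusted p = 4.38e-05; adjusted p = 0.583 with an estimated correlation). NRF2 and glutathione genes had 1 higher and 10 lower of 20, or 1 and 11 adjusted over the list alone (adjusted p = 0.000864; adjusted p = 0.583 with an estimated correlation). The glutathione transferase gene Gstm3 stood at -3.43 ± 0.35.

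Male-biased genes had 1 higher and 9 lower of 20 in fasted against fed KO livers, also adjusted over the list alone (camera adjusted p = 0.00951; adjusted p = 0.661 with an estimated correlation), a call lost without fasted KO replicate 4 (0.0872) or fed KO replicate 1 (0.0603). Nuclear respiratory complex genes had 2 higher and 20 lower of 75, or 2 and 19 adjusted over the list alone (adjusted p = 0.0246; adjusted p = 0.778 with an estimated correlation), and 0 and 31 with library totals. The call was lost without fasted KO replicate 3 (0.207), fed KO replicate 2 (0.0501) or fed KO replicate 4 (0.0625). Mitochondrial genome protein genes had 4 higher and 0 lower of 7, or 5 and 0 adjusted over the list alone (adjusted p = 0.0344; adjusted p = 0.583 with an estimated correlation), a call lost without fasted KO replicate 3 (0.0538), fed KO replicate 1 (0.0669), fed KO replicate 2 (0.0569) or fed KO replicate 3 (0.0646). The other 24 lists were not called, but with library totals integrated stress response (adjusted p = 0.0302) and mitochondrial ribosome genes (0.0257) were. Across genes the fasting effects in WT and KO livers, which share no library, correlated with Pearson r = 0.677 and Spearman rho = 0.701. Called in both genotypes were 1571 genes higher and 1725 lower, against 475.3 and 516.4 for independent lists, and 23 in opposite directions. Here too the shared fit makes the counts for independent lists a reference only.

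**Figure D4:**
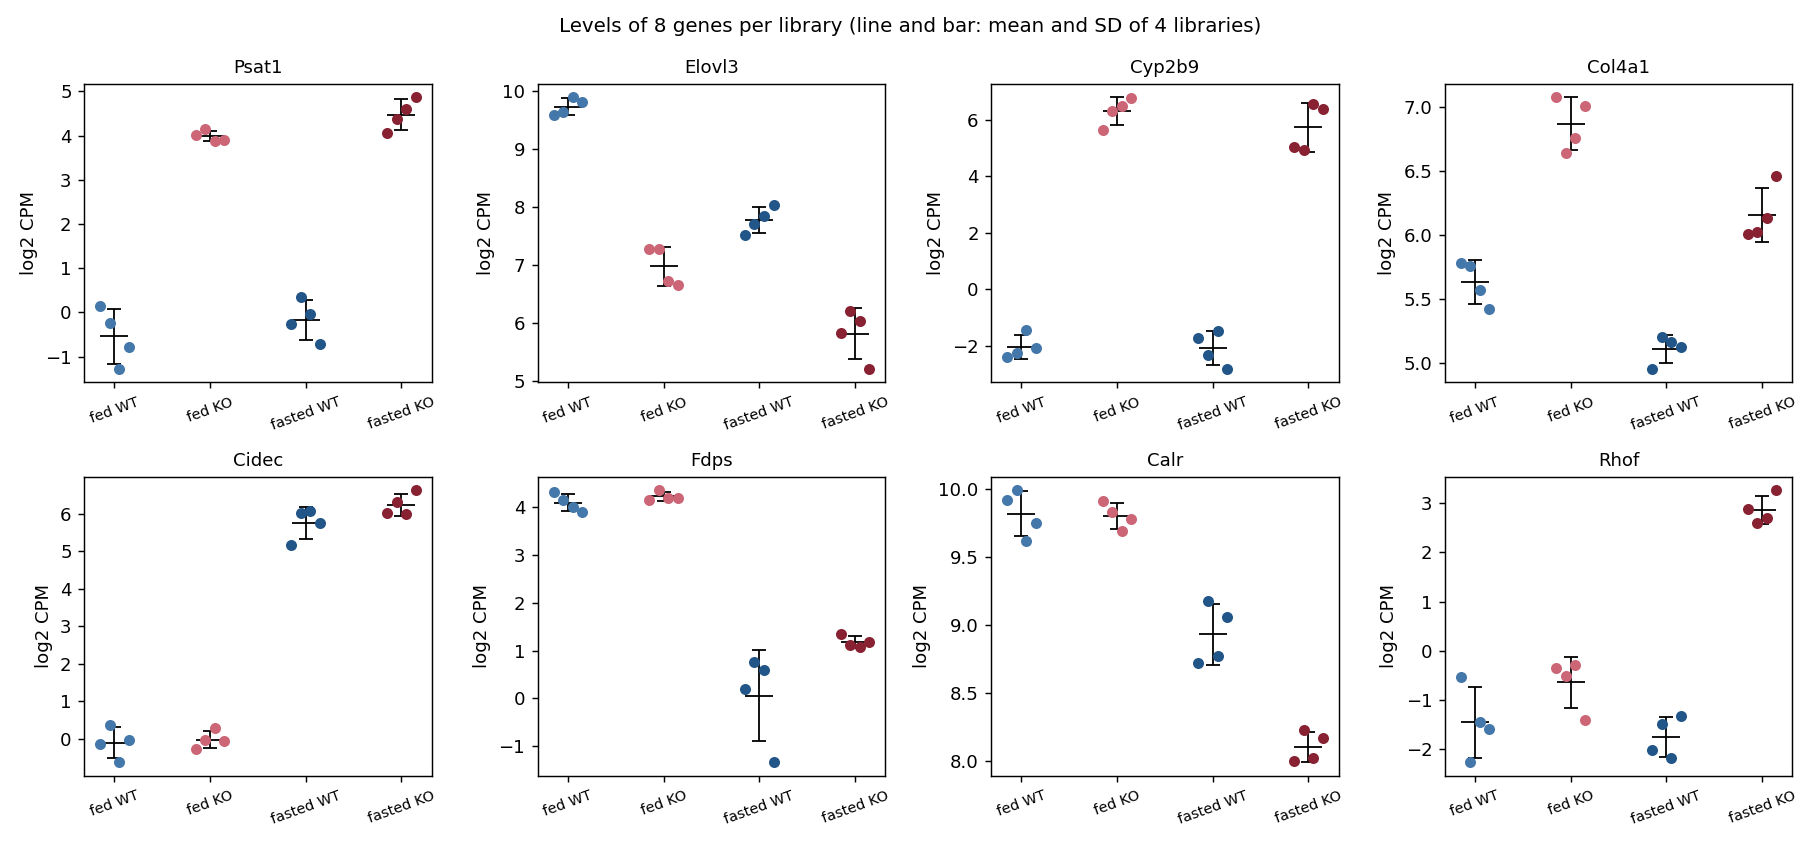
Log2 CPM of 8 genes (one panel each) in the 16 libraries, with the mean and SD of the 4 libraries per group. Psat1, Cyp2b9 and Col4a1 were higher and Elovl3 lower in KO livers of both feeding states, Cidec rose and Fdps fell with fasting in both genotypes, and Calr was lower (-0.84) and Rhof higher (7.28 against 0.218 CPM) in KO than in WT livers after the fast. The fasted WT values include replicates 2 and 4, which carried the most pancreatic transcripts.

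Whether the genotype effect differed between feeding states was tested as the interaction of genotype and feeding. Cyp4a14, at 41.9 ± 27.3 CPM in fed WT and 1362 ± 539 in fed KO livers, reached 11120 ± 1316 and 10952 ± 685 CPM after the fast (SD, n = 4), so that its genotype effect was 5.02 ± 0.61 fed and -0.02 ± 0.51 fasted, an interaction of -5.05 ± 0.77 (SE). Rhof, a small GTPase gene, was at 0.582 ± 0.200 CPM in fed KO and 7.28 ± 1.59 CPM in fasted KO livers, with an interaction of 4.09 ± 0.59. Prok1, which encodes a secreted peptide, had a genotype effect of -1.55 ± 0.23 in fed and 1.22 ± 0.31 in fasted livers. Serpina7 was lower after the fast, at -3.59 ± 0.29 in WT and -1.13 ± 0.24 in KO livers, an interaction of 2.45 ± 0.37.

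With edgeR, 237 genes were called for the interaction, 149 positive and 88 negative, and 2371 genes had an unadjusted p under 0.05; with library totals the split was 88 and 101. Endoplasmic reticulum chaperones had 0 positive and 3 negative of 18 called, or 0 and 7 adjusted over the list alone (camera adjusted p = 1.55e-05; adjusted p = 0.471 with an estimated correlation). Without the pancreas-transcript libraries 0 were called and the median moved from -0.45 to -0.13 (adjusted p = 0.0245). Calr had an interaction of -0.82 ± 0.15 and Pdia3 of -0.66 ± 0.13. Female-biased genes had 0 positive and 3 negative of 17, or 0 and 6 adjusted over the list alone (adjusted p = 5.22e-07; adjusted p = 0.111 with an estimated correlation). Fmo2 stood at -1.53 ± 0.27. Fatty acid oxidation genes had 1 positive and 4 negative of 33, or 2 and 4 adjusted over the list alone (adjusted p = 0.000814; adjusted p = 0.661 with an estimated correlation), and 0 and 1 without the pancreas-transcript libraries (adjusted p = 0.0425). NRF2 and glutathione genes had 1 positive and 2 negative of 20, or 1 and 5 adjusted over the list alone (adjusted p = 0.000363; adjusted p = 0.438 with an estimated correlation). The quinone reductase gene Nqo1 stood at -1.26 ± 0.23 and G6pdx at 1.26 ± 0.24. Pericentral genes had 0 positive and 2 negative of 21, or 0 and 3 adjusted over the list alone (adjusted p = 0.000363; adjusted p = 0.436 with an estimated correlation). Oat stood at -0.84 ± 0.14. Lipogenic genes had 1 positive and 0 negative of 20, or 7 and 0 adjusted over the list alone (adjusted p = 0.000171; adjusted p = 0.436 with an estimated correlation), and integrated stress response genes 2 and 0 of 27, or 5 and 1 adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.471 with an estimated correlation). Chac1 stood at 2.98 ± 0.54.

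For the nuclear respiratory complexes the interaction had 0 of 75 genes called by edgeR and a median of -0.11, and the list was called negative by camera (adjusted p = 4.73e-06; adjusted p = 0.579 with an estimated correlation), with a median of -0.06 without the pancreas-transcript libraries (adjusted p = 0.00468). Bile duct markers (adjusted p = 0.00131; adjusted p = 0.436 with an estimated correlation), drug-metabolising enzymes (0.00186; adjusted p = 0.436 with an estimated correlation) and fetal liver genes (0.00429; adjusted p = 0.438 with an estimated correlation) were called negative with 0, 1 and 1 members called. Matrix genes (0.0102; adjusted p = 0.665 with an estimated correlation) and urea cycle genes (0.0419; adjusted p = 0.788 with an estimated correlation) were called negative too, with 0 and 1 members called. The matrix call was lost without fasted WT replicate 1 (adjusted p = 0.0588), and the urea cycle call without any of 9 of the 16 libraries, up to an adjusted p of 0.197 without fasted KO replicate 3, with the replicate number as a block (0.059) and without the pancreas-transcript libraries (0.101). By fry, a further test of lists, female-biased genes passed (FDR 0.0085) and the other 12 lists called here did not, among them endoplasmic reticulum chaperones (0.175), the respiratory complexes (0.189), fatty acid oxidation (0.328) and matrix genes (0.466). The count of 237 depended on single libraries, ranging from 87 without fasted KO replicate 3 to 523 without fed KO replicate 2, and was 72 without the pancreas-transcript libraries. Of the interaction genes named here, Cyp4a14, Rhof, Prok1, Serpina7, Fmo2, Nqo1 and Oat kept their call without those libraries, and Calr, Pdia3, Chac1 and G6pdx did not (adjusted p from 0.0512 to 0.0821). Their log2 fold changes were then 75.1%, 82.8%, 94.2% and 104% of those with all libraries, and leaving out 2 of 4 libraries also lowers the power of the test.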

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

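The tests of Y-linked genes, single-copy genes, pancreatic transcripts and cell-type lists were chosen only after the results were seen, while the splits of the libraries and the growth hormone targets were chosen before.

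The real groups called far more genes than other splits of the libraries. Each other split of 4 against 4 mixed both real groups, so a real difference widened its spread and lowered its count. The splits cannot tell a genotype or feeding effect from another difference that runs with the groups. In each comparison of 4 against 4 libraries the real split was the 1 of 35 with the most genes: 4299 against at most 25 in the others for the fed genotype effect, 3929 against 1 for the fasted, 4799 against 3 for fasting in WT and 5754 against 4 for fasting in KO. For the interaction, by limma-trend with permuted residuals of the additive model, 259 genes were called in the real data and at most 4 in the others, 1 of 100 draws with the real one included.

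Male-biased genes had 0 higher and 20 lower of 20 in fed and 0 and 19 in fasted KO livers (adjusted p = 0.0868 and 0.271 with an estimated correlation), and female-biased genes 13 higher and 0 lower of 17 in fed and 8 and 2 in fasted KO livers (adjusted p = 0.0232 and 0.275 with an estimated correlation). Female livers among the KO libraries are argued against by 4 Y-linked genes, whose mean in the lowest KO library was 66.7% of the control mean, and by Xist at 4 counts or fewer. Reads shared between near-identical gene copies are argued against for the male-biased genes, since 7 of 7 single-copy members were lower in fed and 6 of 7 in fasted KO livers, but stay open for the female-biased ones, with 7 of 11 higher in fed and 3 of 11 in fasted KO livers; an earlier form pooled all 18 genes (14 fed and 9 fasted in direction) and was divided by sex, with new bounds, after that was seen. Lower growth hormone signalling remains a candidate explanation that the test left open. Igf1, Igfals, Socs2 and Cish had a median of -0.52 in fed and -0.19 in fasted KO livers. In each state 2 of 4 were called lower and 0 higher. Unscaled counts of Igf1 and Igfals were lower in KO livers in both states. Those of Socs2 were 3044 in fed WT and 3842 in fed KO livers, and 1236 and 2051 after the fast. Those of Cish were 2713 and 2190 fed and 596 and 868 fasted. Unscaled counts overstate rises in fasted KO livers, whose libraries were larger. Gene reads averaged 21.61 M in fasted WT and 23.54 M in fasted KO libraries, and TMM factors 0.9175 and 1.044. With library totals the male-biased list kept 20 of 20 lower in fed and 19 of 20 in fasted livers.

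Pancreatic enzyme transcripts appeared in some libraries, with 15 acinar genes summing to 1730 CPM in fasted WT replicate 2, 471 in fasted WT replicate 4, 72.8 in fasted KO replicate 1, 35.3 in fasted WT replicate 3 and 16.9 in fed KO replicate 3, against 1.55 CPM or less elsewhere. Pancreatic tissue sampled with the liver is a candidate source: across these genes the 5 libraries had similar profiles, with a lowest Pearson r of 0.88 over 10 pairs. That value comes from a rewritten test, since the first form, with all 16 listed genes and a limit of 10 CPM, gave 0.184, which met its bound against this source; Cela1 was then found above 0.5 CPM in every fed WT library and left out, and the limit lowered to 5 CPM. A fasting response shared by all livers is argued against. The summed level was 0.543 to 0.932 CPM in fasted WT replicate 1 and fasted KO replicates 2 to 4. It was 0.371 to 1.55 CPM in fed libraries other than fed KO replicate 3. In the test, 4 of 8 fasted libraries lay above that highest fed library, which just meets a bound set after the values were seen. Ctrb1 stood at 269, 68.9, 11.1, 5.13 and 2.15 CPM in the 5 libraries with these transcripts, in the order first given.

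Matrix genes had 25 higher and 1 lower of 34 in fed and 14 and 1 in fasted KO livers, stellate cell markers 10 and 0 of 14 and 7 and 0, and hepatocyte markers 1 higher and 9 lower of 22 and 1 and 12. Adjusted p with an estimated correlation was 0.158 fed and 0.275 fasted for matrix genes, 0.0308 and 0.275 for stellate and 0.293 and 0.275 for hepatocyte markers. A smaller share of hepatocytes alone would raise markers of other cell types alike, but stellate markers averaged 0.47 and endothelial markers 0.08 in the fed state (two-sided permutation p = 8e-05) and 0.26 and 0.04 in the fasted state (p = 0.0437, near the threshold), with 100000 resamples of genes, which are not independent; macrophage and bile duct markers averaged 0.36 and 0.44 in the fed state, closer to the stellate markers, and 0.26 and -0.31 in the fasted state. More stellate cells of unchanged expression could not be told apart from a change within cells: the matrix list averaged 0.66 and 0.54, and its differences from the stellate list had permutation p = 0.157 fed and 0.144 fasted. No other explanation was tested for this pattern.

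The genotype effect on 237 genes differed between feeding states by the interaction test. Among genes named by rule, the interaction log2 fold change was negative for Cyp4a14 (-5.05), Nqo1 (-1.26), Pdia3 (-0.66), Calr (-0.82), Oat (-0.84), Slc25a39 (-0.56) and Fmo2 (-1.53) and positive for Serpina7 (2.45), Inhbe (1.84), Rhof (4.09), Chac1 (2.98), Prok1 (2.77) and G6pdx (1.26), and these 13 calls held without each of the 16 libraries in turn. The other 8 calls were lost without some: C4a (2.32) without any of 11 libraries, with an adjusted p of up to 0.0905, Cyp4a10 (-2.77) without 5 (0.0568), Ehhadh (-1.31) without 11 (0.0764), Fabp5 (2.78) without 6 (0.0703), Acta2 (-1.33) without 13 (0.0981), Atf3 (2.92) without 8 (0.0715), Dmbt1 (-7.73) without 7 (0.0609) and Acot3 (-4.30) without 8 (0.0712). Without fasted WT replicates 2 and 4, which had the most pancreatic transcripts, 14 of the 21 calls were lost. Their log2 fold changes were 75.1% to 106% of those with all libraries, with an SE no smaller for 12 of the 14. Those lost included Calr, Pdia3, Slc25a39, Inhbe, Chac1 and G6pdx, which had held without each single library (edgeR adjusted p from 0.0512 to 0.0826). For Calr the log2 fold change was 75.1% and the SE 94.8% of the value with all libraries.

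A single library lay far from the other 3 of its group in 25 of 492 groups of values tested, where chance gives about 25 (1 in 20). In log2 CPM these were, in fed WT livers, Vmn2r3 in replicate 2 (-2.57), mt-Cytb in replicate 1 (14.17), Hgd in replicate 4 (9.65), Acot2 in replicate 2 (-0.24) and Prok1 in replicate 1 (2.32). In fed KO livers they were Tdo2 (9.76), Cyp2b10 (6.06), Ctrb1 (1.16) and Cela3b (-0.16) in replicate 3, Nupr1 (3.84) and Sdhd (7.29) in replicate 4, Cpt1a in replicate 2 (8.44), and Fabp5 (5.37) and Acta2 (3.63) in replicate 1. In fasted WT livers they were Cyp4a14 in replicate 1 (13.16), Ndufb3 (4.89) and Cyp2f2 (10.41) in replicate 4 and Slc25a20 in replicate 2 (7.84). In fasted KO livers they were Mup12 (1.83), Mup1 (3.73) and Slc25a39 (9.32) in replicate 4, Cyp4a10 (12.88), Cela3b (2.13) and Hsd3b5 (0.71) in replicate 1, and the share of reads from mitochondrial genes in replicate 2 (6.72%).

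The line for reads that aligned to several places, which no gene comparison uses, held 43.3% ± 1.91 of all counts in fed WT and 34.7% ± 3.22 in fed KO livers. It held 43.2% ± 2.49 in fasted WT and 33.7% ± 1.13 in fasted KO livers (SD, n = 4 each). Such a read may be counted there more than once, so these are not shares of reads. The KO libraries lay below the WT libraries in both feeding states (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.0616).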

How the results depend on the processing

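No called log2 fold change of a named gene changed sign under the alternatives run, nor did the camera direction of a called list. With library totals, however, the medians of 2 called lists in the fed genotype effect changed sign, from -0.11 to 0.11 for the respiratory complexes and from -0.19 to 0.03 for bile acid genes, and the interaction split moved from 149 positive and 88 negative to 88 and 101. The count of genes in each two-group contrast stayed within 1.5 times its value except with adjusted p under 0.01, where fewer genes pass by construction: 2449 for the fed and 2332 for the fasted genotype effect, 3114 for fasting in WT and 23 for the interaction. The interaction count of 237 moved most. It was 515 with the DESeq2 Wald test and 72 without the fasted WT libraries with pancreatic transcripts, and without each library in turn it ranged from 87 (without fasted KO replicate 3) to 523 (without fed KO replicate 2). Beyond 1.5 times lay also 155 without fasted KO replicate 2, 126 without fasted KO replicate 4, 118 and 91 without fasted WT replicates 1 and 2, 95 and 116 without fed KO replicates 3 and 4, and 141 and 149 without fed WT replicates 2 and 3; the cause was not tested. With a correlation estimated per list, camera called 3 lists for the fed and 1 for the fasted genotype effect, and 0 for fasting in WT, 0 for fasting in KO and 0 for the interaction, as the larger correlations widen its null. With no filter on low counts the agreement of genotype effects was 0.206; the cause was not tested.

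Without each library in turn, the fed genotype effect called 3202 to 4492 genes, the fasted 3036 to 3771, fasting in WT 4146 to 4691 and fasting in KO 5073 to 5561, the agreement ranged from 0.482 to 0.677, and Slc25a47 from -2.46 to -2.18 in fed and -2.02 to -1.69 in fasted livers. Among values of named genes without 1 library, 198 of 2960 called values lost their call and 54 of 2560 uncalled values gained one. Library totals kept 2863 of 4299, 2818 of 3929, 4407 of 4799, 5035 of 5754 and 171 of 237 calls, in the order fed, fasted, fasting in WT, fasting in KO and interaction. With the replicate number as a block the counts were 4340, 3927, 4818, 5826 and 218 in that order. Same-number libraries of different groups were no more alike than others (24 pairs, r from -0.174 to 0.251, mean 0.023 against -0.008). By fry, 17 of 19 lists called by camera passed for the fed and 19 of 20 for the fasted genotype effect, 8 of 9 for fasting in WT, 10 of 11 for fasting in KO and 1 of 13 for the interaction; in the two-group contrasts the lists that did not pass were, in that order, macrophage markers (FDR 0.084) and fatty acid oxidation (0.109), interferon-stimulated (0.0714), proliferation (0.0507) and respiratory complex genes (0.0786). The fry test asks whether members move 1 way on balance, not whether they move more than other genes. It also passed lists that camera did not call, such as bile duct markers and clock genes for the fed genotype effect (FDR 0.0249 each). In simulated data 47.8% of 1.5-fold changes were recovered.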

Other observations

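The gene families below were picked from a search of 241 symbol stems after the results were seen, with 964 tests in all.

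Stems of cytosolic ribosomal protein genes were over-represented among genes higher in KO livers (one-sided Fisher test adjusted p = 1.52e-17 for Rpl in fed and 8.97e-13 in fasted livers). Of 72 such genes tested, 58 were higher and 0 lower by edgeR in fed KO livers (median 0.48; 69 and 0 with library totals) and 56 and 0 in fasted KO livers (median 0.35; 68 and 0 with library totals). After the fast, 0 were higher and 13 lower in WT livers (0 and 23 with library totals). In KO livers 1 was higher and 38 lower (0 and 47 with library totals), and 0 were called for the interaction. These genes share reads with many processed pseudogenes, so their counts are uncertain.

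Proteasome subunit genes had 0 higher and 25 lower of 38 in fasted KO livers (median -0.27; 1 and 7 with library totals), and 1 and 7 in fed KO livers, which turned to 17 and 2 with library totals. Histone genes, many of whose transcripts lack a poly(A) tail, had 11 higher and 0 lower of 13 in fasted KO livers (median 1.57; 12 and 0 with library totals), and 3 and 0 in fed KO livers (median 0.52; 5 and 0 with library totals).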
